A study of Homo sapiens with 20 samples.

How the data were processed

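RNA from HepG2, a human liver cancer cell line, was measured on 20 Illumina HumanRef-8 version 2 bead arrays. The cells were kept without serum for 4 h. They then received pyrrolidine dithiocarbamate (PDTC, a metal-binding thiol compound used as an inhibitor of NF-kappaB) at 50 µM, interleukin 6 (IL-6) at 20 ng/ml, or vehicle. The PDTC arm and the IL-6 arm each had vehicle arrays and treated arrays at 1, 2, 4 and 8 h, with 2 arrays per group that carry the letters a and b. The series description names 0, 1, 2, 4 and 8 h, and the arrays labelled vehicle, with no time, were taken as those of 0 h. Later vehicle arrays were not part of the design, so a change within an arm includes any effect of time in serum-free medium. Both arms spent the same times in it, and the difference between the arms is free of what they share. It is not free of a deviation of either vehicle set, since each change is measured from its own vehicle. No array combined PDTC with IL-6.

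The authors exported the scanner values with BeadStudio version 1, each arm separately, with no normalization and no background subtraction. Per the file headers, the signal is an intensity on a linear scale, the mean brightness of the beads of a target. The deposited detection score is a fraction, 1 minus the detection p-value. The other deposited column type, of other unit, is the number of beads averaged per target. The deposited series value table holds a z-score per array, that is a score made by the authors from the log10 of the scanner signal minus the mean of the array, divided by the SD of the array. This was settled from the values: all 22182 rows with values matched a scanner row to within 1e-08. A change in that table is in SD units of an array and not in log2 units.

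All values in the report were computed from the 20589 scanner targets. Background was modelled and removed by the normexp method that limma's neqc uses, with an offset of 16, followed by quantile normalization over the 20 arrays and the log2. The mean and SD of the background of each array were estimated from the detection scores of the 18998 targets of 1 probe. For these targets the score was a rank among 708 negative controls, and for the 1591 targets of several probes it was not. A first fit had used all targets and gave background SDs of 86.9 to 231, against 8.15 to 11.5 from the 1-probe targets. That restriction was therefore made after a first set of counts had been seen, and the estimate from all targets is among the alternatives. Targets with a detection p under 0.01 in both arrays of at least 1 group were kept, which left 9126. Where a symbol had several targets the one with the highest mean was used, and 8847 genes were tested, of which 8178 had a symbol and 669 stayed as unnamed targets. Symbols came from the annotation of the array, and positions in the genome were not used here. Close paralogs such as HSPA1A and HSPA1B or the MT1 genes share sequence, and each value belongs to the probe so named.

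Each gene was fitted in limma with 1 mean per group over all 20 arrays, which left 10 residual degrees of freedom, and the spread was moderated with a prior of 6.31 degrees of freedom (eBayes). Each treated group was compared with the vehicle of its own arm by limma's moderated test, and the change under PDTC minus the change under IL-6 was tested at each time. All tests were two-sided. P-values were adjusted by the Benjamini-Hochberg method over all genes within a comparison, and genes with an adjusted p under 0.05 were called, with no fold threshold. Neighbouring times within an arm were compared in the same way. "±" gives the standard error of the log2 change from limma, with 2 arrays in each group. Where the dimmer group was not detected on either array, the change is given as a lower bound, from the lowest signal detected on its arrays. On an array where its own signal lay above that level, its own signal was used. The bound can then equal the fitted change, as for SOCS1, ID1 and PPP2R2C at 1 h of IL-6. The p-values measure the spread between arrays of a group, and whether these were separate cultures or repeats of 1 RNA is not stated in the labels, so this spread may be technical.

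Before the data were examined, 27 gene lists were fixed from textbook knowledge, with 592 entries, of which 540 were named on the array. Each was tested against all other genes with limma's camera at a preset correlation of 0.01, and p-values were adjusted over the 216 tests of 27 lists in 8 comparisons. The tests were repeated with a correlation estimated for each list and with fry, which asks whether the genes of a list move, on balance, one way. For each list the members that passed the test over all genes were counted, and those that passed when adjusted over the list alone. Some genes are in several lists, for example IRF1 in the IL-6, interferon and NF-kappaB lists. Sets of genes called in both arms were compared with Fisher's exact test, two-sided and adjusted over 16 sets.

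The genes to be named were also fixed by rule. For each comparison these were up to 4 of the largest rises and up to 4 of the largest falls among called genes with a symbol, with both treated arrays on the same side of both vehicle arrays and detected in the higher group. The rule added, for each called list, up to 4 members with the largest change at the time of its smallest p, and 20 fixed genes of special interest. For the difference between the arms it took the 4 largest of each sign. Genes named outside the rule are marked as chosen after their values were seen.

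The letters a and b were checked as pairs. The differences of a minus b were correlated across genes between the groups of an arm. In the PDTC arm they ranged from -0.421 to 0.378, with 4 of 10 above 0.1, and in the IL-6 arm from -0.264 to 0.167, with 2 of 10 above 0.1. The letters were therefore not used as pairs.

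The fit was tested on simulated data in which some genes were shifted by known amounts. At log2 changes of 0.5, 1 and 2 it recovered 20.9%, 82.1% and 100% of them in the PDTC 4 h comparison and 19.4%, 77.6% and 100% in the IL-6 4 h comparison, and of the genes called 6.8% and 6.3% were unchanged ones. The simulated arrays varied independently around a common vehicle mean, with the same SD in every group. They held no gap between vehicle sets and no deviant array, so these shares do not carry over to the measured calls. With 2 arrays per group their number limits the precision.

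The alternatives fixed beforehand were normexp with an offset of 50, no background correction, scaling to a common median, quantile normalization within each arm, the series value table, no detection filter, detection on all 20 arrays, the mean of all probes of a gene, a trended and robust spread, each arm fitted alone, the letters as a block, array weights, a 1.5-fold threshold, an estimated correlation, an F test over the 4 times, the 100 smallest p-values for the IL-6 genes, and each array left out in turn. Chosen after the data had been seen were the background from all targets, the detection of targets of several probes taken from their signal, and a fit without PDTC vehicle a and PDTC 8 h a. R 4.3.3, limma 3.58.1, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used.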

Results

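RNA levels were measured in HepG2 liver cancer cells at 1, 2, 4 and 8 h of PDTC at 50 µM or of IL-6 at 20 ng/ml, with vehicle, taken as 0 h, in each arm and 2 arrays in each of the 10 groups. The series is about the action of PDTC on IL-6 signalling, and the arms answer which genes each agent moved alone. The mean scanner signal lay between 225 and 425, and 6839 to 8876 of 20589 targets were detected per array. In the PDTC arm the mean signal was 399 and 425 in vehicle and 258 and 326 at 8 h. Normalized log2 values of the arrays of a pair correlated across genes with r of 0.958 (PDTC 8 h) to 0.994 (PDTC 2 h), and genes are not independent replicates. PDTC 8 h a had the fewest detected targets of its arm, 7033. All changes are relative to the middle of the genes on each array, since quantile normalization removes any shift of all genes together. With scaling to a common median instead, the median of all genes moved by -0.27, -0.32, -0.49 and -0.68 at 1, 2, 4 and 8 h of PDTC and by 0.08, 0.41, 0.38 and 0.33 at those times of IL-6 (log2). The list means given below under median scaling include this shift. Camera compares a list with the other genes, and no called list changed its camera direction under that scaling.

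**Figure D1:**
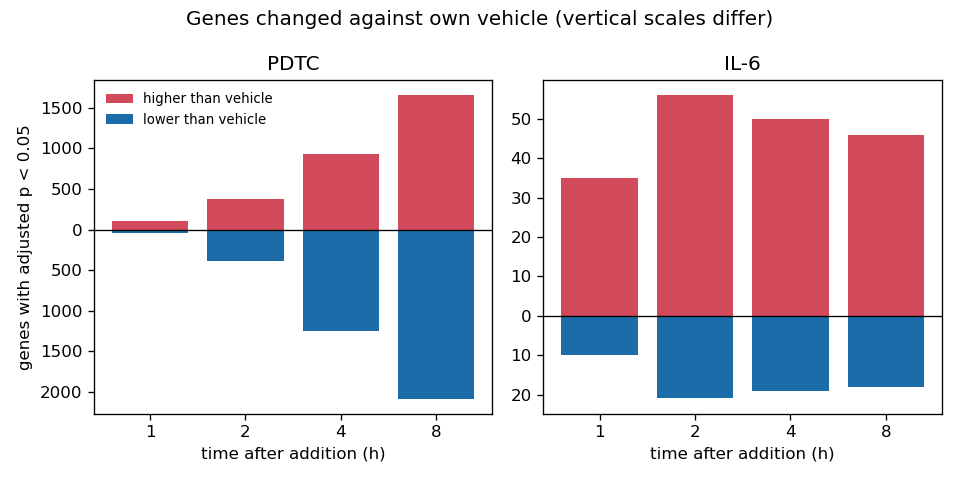
Bars show the number of genes called higher (up) or lower (down) than the vehicle of the same arm at 1, 2, 4 and 8 h, of 8847 tested with 2 arrays per group. The vertical scales differ: under PDTC the counts went from 112 higher and 42 lower at 1 h to 1656 higher and 2080 lower at 8 h, while under IL-6 no time had more than 56 higher or 21 lower. Under median scaling only 9.8% and 7.1% of the genes called at 4 and 8 h of PDTC were higher, and 31.4% and 32.2% in the series value table, against 42.7% and 44.3% here.

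At 1 h of PDTC, genes of the heat shock, metal and immediate early responses had already risen steeply. HSPA1A, an inducible HSP70 chaperone, rose by 4.83 ± 0.55 (log2; adjusted p = 4.27e-05), although its 2 vehicle arrays lay at -1.04 and 1.04 around their mean. MT1B and MT1M, metal-binding metallothioneins, rose by 4.66 ± 0.14 (adjusted p = 2.08e-12) and 4.24 ± 0.14 (adjusted p = 6.22e-12). FOS, a subunit of the transcription factor AP-1 that was not detected in vehicle, was at least 25.6-fold higher. The largest falls were those of PHLDA1 (-1.35 ± 0.17), DEPP1 (-1.24 ± 0.15), AXIN2 (-1.18 ± 0.15), a feedback regulator of Wnt signalling, and SP5 (-1.18 ± 0.18), a transcription factor and Wnt target, with adjusted p-values of 0.000127, 6.67e-05, 0.000127 and 0.00107. In total 154 genes passed, 112 higher and 42 lower.

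Of the 20 immediate early genes measured 11 rose, 0 fell and 9 were not called (14 rose when adjusted over the list alone; list adjusted p = 1.21e-25), among them EGR1 (4.22 ± 0.16) and DUSP1 (3.40 ± 0.14), a phosphatase of MAP kinases. In the metal response list 8 of 10 rose and 2 were not called (8 adjusted over the list alone; 8.57e-22), with MT1E at 2.46 ± 0.22 and MT1X at 1.86 ± 0.13. Of 25 heat shock proteins and chaperones 9 rose and 16 were not called (14 adjusted over the list alone; 1.21e-15), including the co-chaperones DNAJB1 (2.41 ± 0.14) and BAG3 (1.29 ± 0.17). In the list of ATF4 and integrated stress response genes 6 of 17 rose and 11 were not called (13 adjusted over the list alone; 2.54e-14). DDIT4, an inhibitor of mTOR signalling, was higher by 3.40 ± 0.17, PPP1R15A, a subunit that directs dephosphorylation of eIF2α, by 3.20 ± 0.18, and DDIT3, the transcription factor CHOP, by 2.28 ± 0.19.

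Of 16 NF-kappaB target genes 7 rose, 0 fell and 9 were not called at 1 h of PDTC (8 adjusted over the list alone; list adjusted p = 2.25e-13). IRF1, an interferon regulatory factor, rose by 2.07 ± 0.17, NFKBIA, the inhibitor IκBα, by 1.76 ± 0.13, CXCL8, the chemokine IL-8, by 1.54 ± 0.20 and IER3 by 1.51 ± 0.13. Of 10 histone genes 4 rose and 6 were not called (7 rose and 1 fell adjusted over the list alone; 1.08e-06), with H2AC6 at 1.46 ± 0.19 and H3C4 at 1.22 ± 0.19. The list of IL-6, JAK and STAT3 targets was called higher (8.04e-05; adjusted p = 0.0731 with an estimated correlation) from 4 rises among 19 genes, 15 not called and 6 adjusted over the list alone. One of the 4 was GADD45B, a stress-induced regulator of growth, at 2.51 ± 0.23. In the interferon list 1 of 14 rose, IRF1, and 13 were not called, also 1 adjusted over the list alone (0.00289; adjusted p = 0.192 with an estimated correlation). The count of 154 genes became 66 without PDTC vehicle a, 533 without vehicle b, 70 and 82 without 1 h a or b, and 282 and 295 without 8 h a or b. It became 253 with an offset of 50, 283 without background correction, 49 with median scaling, 80 with each arm fitted alone, and 94 without vehicle a and 8 h a together. The excess of rises depended on the background: 142 were higher and 141 lower without background correction, and 110 and 155 with the background from all targets.

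At 2 h of PDTC the same kinds of genes stood higher and more were called. MT1B rose by 5.97 ± 0.14 (adjusted p = 3.85e-14), HSPA1A by 5.65 ± 0.55 (2.72e-06) and MT1M by 5.32 ± 0.14 (1.65e-13), and FOS was at least 31.6-fold higher (3.33e-12). AXIN2 fell by 2.28 ± 0.15 (1.81e-08), SP5 by 1.80 ± 0.18 (3.6e-06), DEPP1 by 1.76 ± 0.15 (4.29e-07) and DKK1, a secreted inhibitor of Wnt signalling, by 1.69 ± 0.28 (0.00108). HMOX1, heme oxygenase 1, was higher by 3.46 ± 0.21. In total 761 genes passed, 379 higher and 382 lower.

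Heat shock genes now included 18 rises among 25, with 7 not called (21 adjusted over the list alone; list adjusted p = 3.16e-29). HSPA6, an HSP70 chaperone not detected in vehicle, was at least 30.3-fold higher and HSPA1B rose by 3.09 ± 0.16. Of the immediate early genes 16 of 20 rose and 4 were not called (16 adjusted over the list alone; 1.04e-28), with EGR1 at 4.50 ± 0.16, DUSP1 at 4.41 ± 0.14 and ZFP36, which speeds the decay of AU-rich mRNAs, at 2.73 ± 0.20. In the ATF4 list 12 of 17 rose and 5 were not called (13 adjusted over the list alone; 3.21e-20), led by PPP1R15A (4.24 ± 0.18), DDIT4 (3.92 ± 0.17) and DDIT3 (3.57 ± 0.19). MTHFD2, a mitochondrial folate enzyme, rose by 2.66 ± 0.77 but was not detected on every array. The metal list had 8 rises among 10 and 2 not called (9 adjusted over the list alone; 7.18e-19).

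NF-kappaB targets rose in 11 of 16 cases at 2 h and 5 were not called (11 adjusted over the list alone; list adjusted p = 1.51e-16), with CXCL8 at 2.32 ± 0.20 and IER3 at 2.19 ± 0.13. Of the histones 5 of 10 rose and 5 were not called (7 rose and 1 fell adjusted over the list alone; 5.15e-06). Of the IL-6 and STAT3 list 8 of 19 rose and 11 were not called (8 rose and 2 fell adjusted over the list alone; 8.04e-06). Cholesterol synthesis genes were called higher as a list (0.0192; adjusted p = 0.0631 with an estimated correlation), although their mean was -0.09 under median scaling, from 3 rises among 17, 14 not called and 4 adjusted over the list alone. MSMO1, a sterol oxidase, rose by 1.40 ± 0.33 and HMGCS1, which makes the precursor of mevalonate, by 0.87 ± 0.15. The hypoxia list was called higher (0.0192; adjusted p = 0.11 with an estimated correlation), with a mean of -0.08 under median scaling, from 3 rises among 18 and 15 not called (4 rose and 2 fell adjusted over the list alone). The interferon list was called higher (0.029; adjusted p = 0.315 with an estimated correlation), with a mean of -0.01 under median scaling, from 3 rises among 14 and 11 not called (3 adjusted over the list alone). The count of 761 genes became 211 without PDTC vehicle a (172 higher and 39 lower), 196 without 2 h a (159 and 37) and 346 without 2 h b (211 and 135). It was 235 with median scaling, 299 with each arm fitted alone, 1175 with array weights and 266 without vehicle a and 8 h a together.

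**Figure D2:**
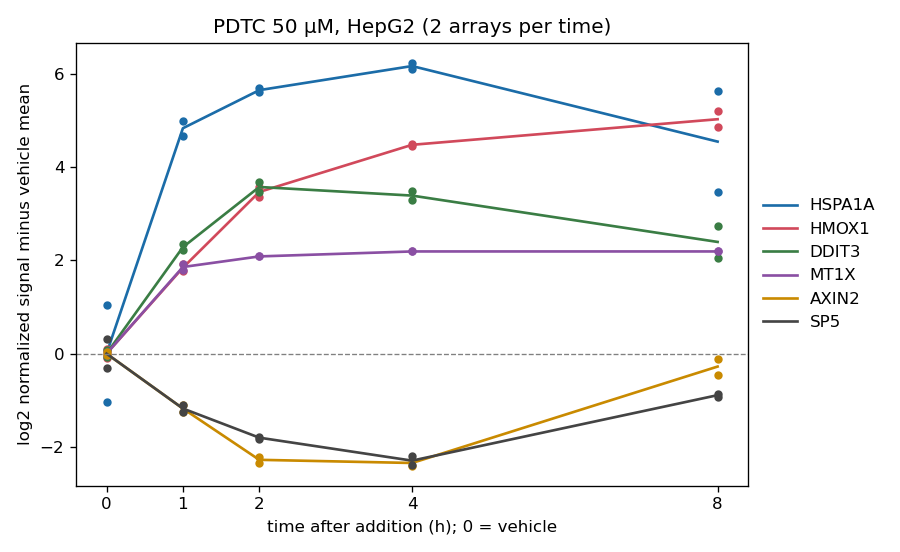
Log2 normalized signal minus the mean of the 2 vehicle arrays (vertical) against hours of PDTC (horizontal); points are single arrays and lines join the group means of the 2 arrays. HSPA1A, HMOX1, DDIT3 and MT1X lay above vehicle at every time, and AXIN2 and SP5 were lowest at 4 h, by -2.34 and -2.29.

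By 4 h of PDTC 24 of the 25 measured heat shock and chaperone genes were higher, and HMOX1 rose by a further 1.01 ± 0.21 over 2 h (adjusted p = 0.0138). MT1B rose by 6.85 ± 0.14 (adjusted p = 4.12e-15), HSPA1A by 6.16 ± 0.55 (4.34e-07) and MT1M by 5.77 ± 0.14 (4.34e-14), and HSPA6 was at least 68.3-fold higher (5.16e-14). AXIN2 fell by 2.34 ± 0.15 (5.46e-09), SP5 by 2.29 ± 0.18 (9.46e-08), DEPP1 by 1.80 ± 0.15 (1.57e-07) and SESN1, a p53 target of the sestrin family, by 1.70 ± 0.25 (0.000147). HAMP, which encodes the iron hormone hepcidin, rose by 1.53 ± 0.22. In total 2175 genes passed, 929 higher and 1246 lower.

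Of the 25 heat shock genes 24 rose and 1 was not called (25 adjusted over the list alone; list adjusted p = 4.97e-30), with BAG3 at 3.97 ± 0.17 and DNAJB1 at 3.85 ± 0.14. Of the immediate early genes 17 rose, 1 fell and 2 were not called (18 rose and 1 fell adjusted over the list alone; 7.69e-22), with DUSP1 at 4.50 ± 0.14 and ZFP36 at 3.42 ± 0.20. In the ATF4 list 14 rose and 3 were not called (15 adjusted over the list alone; 1.81e-16), and PPP1R15A stood at 4.86 ± 0.18. The metal list kept 8 rises of 10 and 2 not called (8 adjusted over the list alone; 1.23e-12). Of the NF-kappaB targets 11 rose and 5 were not called (11 adjusted over the list alone; 3.24e-09), with CXCL8 at 3.07 ± 0.20 and NFKBIA at 0.79 ± 0.13.

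In the IL-6, JAK and STAT3 list 10 of 19 rose, 1 fell and 8 were not called (10 rose and 2 fell adjusted over the list alone; list adjusted p = 1.15e-06), with GADD45B at 3.72 ± 0.23. Histones had 7 rises, 1 fall and 2 not called (7 and 1 adjusted over the list alone; 0.000203). The NRF2 antioxidant list was called higher (0.0217; adjusted p = 0.0631 with an estimated correlation) from 6 rises, 1 fall and 13 not called among 20, the same numbers adjusted over the list alone. HMOX1 was higher by 4.48 ± 0.21, GCLM, a subunit of the enzyme that limits glutathione synthesis, by 1.96 ± 0.17 and TXNRD1, thioredoxin reductase 1, by 1.49 ± 0.14. The interferon list was called higher (0.029; adjusted p = 0.315 with an estimated correlation), with a mean of -0.11 under median scaling, from 4 rises and 10 not called (4 adjusted over the list alone), one of them BST2, an antiviral membrane protein, at 1.07 ± 0.17. The count of 2175 genes became 944 without PDTC vehicle a (522 higher), 973 without 4 h b (530 higher) and 1393 without vehicle a and 8 h a together. With median scaling 3207 genes were called.

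At 8 h of PDTC the metallothionein genes MT1B and MT1M and the stress genes HSPA6 and HMOX1 had the largest rises. MT1B rose by 7.69 ± 0.14 (adjusted p = 6.45e-16), MT1M by 6.72 ± 0.14 (3.73e-15) and HMOX1 by 5.02 ± 0.21 (3.81e-11), and HSPA6 was at least 58.5-fold higher (9.36e-14). GTF3C2, a subunit of transcription factor IIIC, fell by 2.28 ± 0.39 (0.0003), and MYO10, an unconventional myosin, by 2.22 ± 0.42 (0.000641). PDHX, a component of the pyruvate dehydrogenase complex, was at -2.02 ± 0.50 (0.00468) and ALCAM, a cell adhesion molecule, at -1.97 ± 0.38 (0.000791). AXIN2 was near vehicle again (-0.28 ± 0.15, adjusted p = 0.14). In total 3736 genes passed, 1656 higher and 2080 lower. PDTC vehicle, from which all changes under PDTC are measured, differed from IL-6 vehicle in 3123 genes. How many PDTC calls lay toward the level of IL-6 vehicle was not counted.

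The NRF2 antioxidant list had 9 rises, 3 falls and 8 not called at 8 h (the same numbers adjusted over the list alone; list adjusted p = 0.000493). SLC7A11, the cystine transporter, was not detected in vehicle and was at least 6.58-fold higher, GCLM rose by 2.65 ± 0.17 and TXNRD1 by 2.63 ± 0.14. Heat shock genes had 22 rises and 3 not called (22 adjusted over the list alone; 3.21e-20), and metal response genes 9 rises and 1 fall (the same adjusted over the list alone; 1.48e-08), with MT2A at 0.88 ± 0.14. Immediate early genes had 15 rises, 1 fall and 4 not called (16 and 1 adjusted over the list alone; 1.71e-10), with FOS now at least 6.04-fold higher. The ATF4 list had 13 rises, 1 fall and 3 not called (14 and 1 adjusted over the list alone; 6.71e-09). The IL-6, JAK and STAT3 list was called higher (0.0017; adjusted p = 0.156 with an estimated correlation) from 11 rises, 1 fall and 7 not called (11 and 1 adjusted over the list alone). STAT3 itself, the transcription factor that IL-6 activates, rose by 0.53 ± 0.17 (adjusted p = 0.0183), but was lower by -0.14 under median scaling.

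Among negative acute phase proteins, liver secretory proteins that fall in inflammation, 6 of 13 fell and 7 were not called at 8 h of PDTC (6 adjusted over the list alone; list adjusted p = 0.0212, and adjusted p = 0.195 with an estimated correlation). SERPINA7, which carries thyroxine, fell by 1.17 ± 0.13, APOA1, the main protein of high-density lipoprotein, by 0.59 ± 0.12 and ALB, albumin, by 0.57 ± 0.16. In the series value table the direction turned for APOA1 (0.85 SD units), ALB (0.29) and the list (0.164). APOA1 was among the brightest targets, where quantile normalization fixes the value of each rank: its scanner signals were 31813 and 38017 in PDTC vehicle and 18566 and 24451 at 8 h. Of the positive acute phase proteins the fibrinogen chains fell, FGA by 0.83 ± 0.14, FGB by 0.70 ± 0.20 and FGG by 0.87 ± 0.16, as did HP, haptoglobin, by 0.48 ± 0.19 (adjusted p = 0.0485), while HAMP rose by 1.96 ± 0.22 and SERPINA3 was at 0.12 ± 0.14 (adjusted p = 0.494).

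Fatty acid synthesis genes fell in 7 of 12 cases at 8 h and 5 were not called (8 adjusted over the list alone; list adjusted p = 0.029, and adjusted p = 0.194 with an estimated correlation). GPAM, the first enzyme of glycerolipid synthesis, fell by 1.62 ± 0.20, SCD, stearoyl-CoA desaturase, by 1.20 ± 0.17 and the lipogenic transcription factors MLXIPL and SREBF1 by 0.70 ± 0.17 and 0.69 ± 0.19. Cholesterol synthesis genes, higher as a list at 2 h, had 1 rise, 9 falls and 7 not called (the same adjusted over the list alone; 0.0488, and adjusted p = 0.118 with an estimated correlation), with MSMO1 at -0.85 ± 0.33 and HMGCS1 at 0.00 ± 0.15. The histone list was called higher (0.0424; adjusted p = 0.118 with an estimated correlation), with a mean of -0.06 under median scaling, from 6 rises, 2 falls and 2 not called (the same adjusted over the list alone). The interferon list was called higher (0.011; adjusted p = 0.271 with an estimated correlation), with a mean of -0.16 under median scaling, from 5 rises and 9 not called (5 adjusted over the list alone), with BST2 at 1.37 ± 0.17. The count of 3736 genes became 2365 without PDTC vehicle a, 2252 without 8 h a, 1411 without both, and 1820 with array weights. Across the 4 times 4354 genes were called at least once and 126 at every time; without vehicle a the first count was 2641.

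Within the PDTC arm, 67 genes differed between 2 h and 1 h (65 higher at 2 h), 190 between 4 h and 2 h (156 higher at 4 h) and 1155 between 8 h and 4 h (623 higher at 8 h). From 4 to 8 h MT1B went up by a further 0.83 ± 0.14 (adjusted p = 0.00133), SLC7A11 by 1.51 ± 0.15 (1.54e-05) and TXNRD1 by 1.14 ± 0.14 (0.000103). FOS (-1.81 ± 0.18, 1.35e-05), DDIT4 (-1.69 ± 0.17, 2.2e-05) and CXCL8 (-1.15 ± 0.20, 0.00173) went down, and AXIN2 (2.07 ± 0.15, 1.1e-06) and SP5 (1.40 ± 0.18, 0.000136) came back up. MT1X and MT2A ranked among the brightest targets, so quantile normalization limits their changes: the scanner signals of MT2A were 20064 and 19631 in vehicle and 44303 and 48146 at 8 h. ATF3, a stress-induced transcription factor of the fixed gene set, had a target of several probes and did not pass the detection filter. With detection taken from the signal, an alternative chosen after the data were seen, it rose by 2.20, 3.72, 3.82 and 2.74 at 1, 2, 4 and 8 h (standard error 0.17, adjusted p from 8.44e-11 to 4.27e-07).

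At 1 h of IL-6, known targets of the cytokine rose sharply. IRF1 rose by 2.53 ± 0.17 (adjusted p = 4.34e-07), HAMP by 2.47 ± 0.22 (1.02e-05) and CEBPD, a transcription factor of the acute phase response, by 2.37 ± 0.17 (8.06e-07), and GADD45B, not detected in vehicle, was at least 3.52-fold higher (3.51e-05). DDIT4 fell by 1.19 ± 0.17 (0.00155), ANKRD37, a hypoxia-inducible gene, by 1.08 ± 0.14 (0.000307) and CLK1, a kinase of splicing factors, by 0.94 ± 0.19 (0.0335), and PPP2R2C, a regulatory subunit of phosphatase 2A, was at least 2-fold lower (0.00177). In total 45 genes passed, 35 higher and 10 lower.

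Of 19 measured IL-6, JAK and STAT3 genes 4 rose, 0 fell and 15 were not called at 1 h (8 rose and 1 fell adjusted over the list alone; list adjusted p = 9.36e-10). SOCS1, a feedback inhibitor of JAK kinases, was at least 2.73-fold higher. STAT3 was at 0.02 ± 0.17 (adjusted p = 1). Of 18 positive acute phase genes 2 rose, HAMP and HP, and 16 were not called (4 adjusted over the list alone; 1.38e-05). HP rose by 1.32 ± 0.19 (adjusted p = 0.00123), while SERPINA3 (0.57 ± 0.14, 0.0946), FGA (0.52 ± 0.14, 0.172) and FGB (0.33 ± 0.20, 0.867) did not pass. In the iron and BMP list 2 of 12 rose, HAMP and ID1, and 10 were not called (2 adjusted over the list alone; 0.000551), and ID1, an inhibitor of DNA binding and a BMP target, was at least 3.25-fold higher. The metal list was called higher (2.93e-05) with 0 of its 10 genes passing over all genes and 6 adjusted over the list alone. For this list PDTC vehicle, also untreated, lay 0.47 above IL-6 vehicle, so an effect of IL-6 on it was not separated from that gap.

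NF-kappaB targets were called higher as a list at 1 h of IL-6 (adjusted p = 0.00131, and adjusted p = 0.0631 with an estimated correlation) from 2 rises among 16, IRF1 and IER3, with 14 not called (5 adjusted over the list alone). IER3 rose by 1.00 ± 0.13. Immediate early genes had 2 rises and 18 not called (4 adjusted over the list alone; 0.0278, and adjusted p = 0.315 with an estimated correlation), and EGR1, not detected in vehicle, was at least 1.69-fold higher. The interferon list had 1 rise, IRF1, and 13 not called (2 adjusted over the list alone; 0.0321, and adjusted p = 0.315 with an estimated correlation). DNAJB1 rose by 1.31 ± 0.14 (adjusted p = 4.53e-05), and HMOX1 by 0.97 ± 0.21 (0.0485). Of the 45 genes called at 1 h, 35 had changed toward the level of PDTC vehicle, against 57.3% of all genes, counts that share the IL-6 vehicle arrays. Equally many genes were also picked on the arrays of one letter and measured on the other. There the gap was -0.207 and 0.592 times the IL-6 change. For DNAJB1, HMOX1 and the genes that fell, an effect of IL-6 was not separated from the gap between the vehicle sets. SOCS3, JUNB, CRP and SAA1, also fixed as genes of interest, were not detected on any array. The count of 45 genes became 70 without IL-6 vehicle a and 28 without vehicle b, 15 with median scaling, all of them higher, and 26 in the series value table (24 higher). DDIT4, ANKRD37, PPP2R2C, CLK1 and HMOX1 did not pass under either of the last settings, HP did not with median scaling (1.55) and GADD45B did not in the series value table (0.711 SD units).

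**Figure D3:**
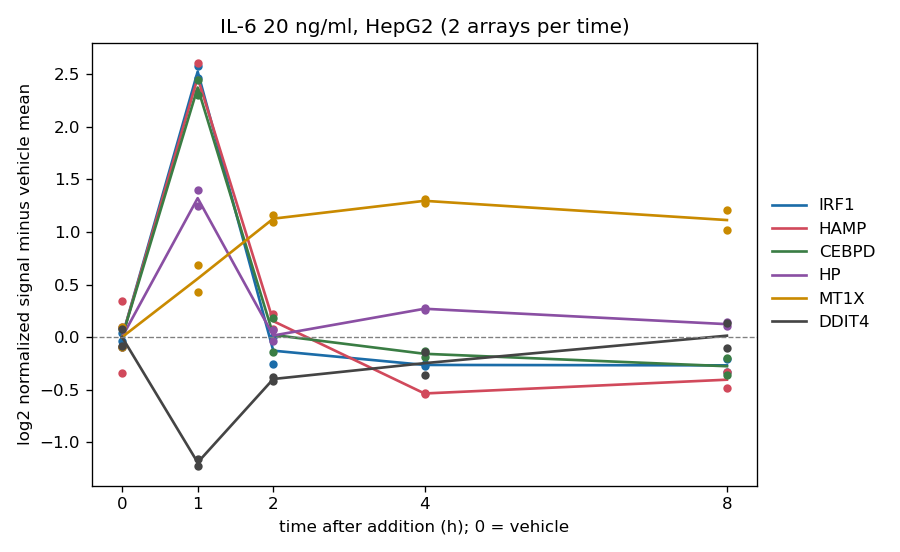
Log2 normalized signal minus the mean of the 2 vehicle arrays (vertical) against hours of IL-6 (horizontal); points are single arrays and lines join the group means of the 2 arrays. IRF1, HAMP, CEBPD and HP were highest at 1 h, at 2.53, 2.47, 2.37 and 1.32, and did not differ from vehicle by the test at 2, 4 and 8 h. MT1X was higher at 2, 4 and 8 h, at 1.13, 1.30 and 1.11.

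At 2 h of IL-6 genes that had risen at 1 h were lower again, and the metallothionein genes MT1X and MT1M were higher than in vehicle. Tested directly between 2 h and 1 h, 50 genes differed, 38 of them lower at 2 h, including IRF1 (-2.66), CEBPD (-2.35), HAMP (-2.32), ID1 (-2.18, detected on 1 of the 2 arrays at 2 h), IER3 (-1.56) and HP (-1.31), with adjusted p from 2.02e-07 to 0.00135. GADD45B and SOCS1, not detected again at 2 h, were also lower than at 1 h (4.8e-05 and 0.0014). MT1X rose over vehicle by 1.13 ± 0.13 (adjusted p = 0.000629) and MT1M by 0.77 ± 0.14 (0.0222). The largest rises over vehicle were those of POLD3 (a DNA polymerase subunit), TCF3, LRIG1 and PURB, the first 3 at least 2.05-, 1.74- and 1.65-fold higher and PURB by 1.19 ± 0.27 (adjusted p of 0.000454, 0.0483, 0.00876 and 0.0491). BHLHE40, a clock-related repressor, fell by 1.21 ± 0.17 (0.00876), CREM was at least 1.78-fold lower (0.00876) and H2AC14, a histone gene, fell by 0.96 ± 0.21 (0.0412). PDTC vehicle, also untreated, differed from IL-6 vehicle the same way: it was higher for POLD3 (0.47), TCF3 (1.49), LRIG1 (1.26), PURB (1.37), MT1X (0.75) and MT1M (0.40) and lower for BHLHE40 (-1.29), CREM (-0.96) and H2AC14 (-1.34). An effect of IL-6 on these genes was not separated from that gap.

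In total 77 genes passed at 2 h of IL-6, 56 higher and 21 lower, and 87% of them were dimmer than the median tested gene, against 35.6% at 1 h. In the metal list 3 of 10 rose and 7 were not called (7 adjusted over the list alone; list adjusted p = 1.95e-06). In the series value table neither MT1X (0.685, 0.859 and 0.691 SD units at 2, 4 and 8 h) nor the list (0.13 and 0.15 at 2 and 4 h) passed. The hypoxia list was called lower (0.00411; adjusted p = 0.0571 with an estimated correlation), with a mean of 0.22 under median scaling, from 1 fall, ANKRD37 (-0.63 ± 0.14), and 17 not called (2 adjusted over the list alone). An effect of IL-6 on this list or on the metal list was not separated from the gap between the vehicle sets. The list of cytochromes P450 and drug transporters was called higher (0.0331; adjusted p = 0.271 with an estimated correlation) with 0 of 9 genes passing and 2 adjusted over the list alone. Its largest changes were those of CYP3A7 and CYP1A1, which were not detected in vehicle. The count of 77 fell to 18 with an offset of 50, 14 without background correction, 1 with median scaling and 5 with quantile normalization within the arm. It fell to 7 for genes detected on all 20 arrays, where 14 of the 77 were still tested. In the series value table it was 0 by limma (1591 at an unadjusted p under 0.05). It became 7 without IL-6 vehicle b, 207 without vehicle a, 3 and 4 without 2 h a or b. It was 50, 50, 47 and 45 without PDTC 1 h a, 1 h b, 2 h a or 2 h b, and 216 and 208 without PDTC 8 h a or b.

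At 4 h of IL-6 MT1X had the largest rise, 1.30 ± 0.13 (adjusted p = 0.000179), and MT1M stood at 0.77 ± 0.14 (0.0223). TXNRD1 rose by 0.69 ± 0.14 (0.028). PIGS, of GPI anchor synthesis, rose by 1.29 ± 0.27 (0.0329), LRIG1 was at least 1.63-fold (0.0132) and MCCC2, a subunit of a leucine-degrading enzyme, at least 2.09-fold higher (0.0223). DGKZ, a diacylglycerol kinase, was at least 1.79-fold lower (0.0177), LINC02910 at least 1.66-fold (0.034) and BTLA at least 1.79-fold (0.0257), and DMRTC1 fell by 0.93 ± 0.17 (0.0199). PDTC vehicle also differed from IL-6 vehicle in the direction of these changes for MCCC2, PIGS (1.17), DGKZ (-1.12), LINC02910 (-0.87), BTLA (-0.57) and DMRTC1 (-0.71). HAMP (-0.54 ± 0.22, 0.285), IRF1 (-0.26 ± 0.17, 0.51), CEBPD (-0.16 ± 0.17, 0.739) and HP (0.27 ± 0.19, 0.56) did not pass.

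In total 69 genes passed at 4 h of IL-6, 50 higher and 19 lower. The metal list had 2 rises and 8 not called (7 rose and 1 fell adjusted over the list alone; list adjusted p = 1.46e-05), and the NRF2 list 2 rises and 18 not called (4 adjusted over the list alone; 0.011). Hypoxia genes were lower as a list (0.000194), with a mean of 0.11 under median scaling, from 3 falls and 15 not called (4 adjusted over the list alone), namely ANKRD37 (-0.81 ± 0.14), PFKFB4 (-0.79 ± 0.17), a glycolytic regulator, and NDRG1 (-0.71 ± 0.16). Of the 69 genes 67 had changed toward the level of PDTC vehicle, against 70.2% of all genes. An effect of IL-6 on the metal, hypoxia and NRF2 genes was not separated from the gap between the vehicle sets. NF-kappaB targets were lower as a list (0.0225; adjusted p = 0.184 with an estimated correlation), with a mean of 0.14 under median scaling and 0 of 16 genes passing (1 fell adjusted over the list alone). Between 4 h and 2 h limma called 0 genes (196 at an unadjusted p under 0.05). The count of 69 fell to 32, 22, 1, 9, 12 and 6 under the same alternatives in the order given for 2 h. It became 2 without IL-6 vehicle b, 256 without vehicle a, 7 and 1 without 4 h a or b, and 205 without PDTC 8 h a or without 8 h b.

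At 8 h of IL-6 MT1X was still higher by 1.11 ± 0.13 (adjusted p = 0.00148) and MT1M by 0.70 ± 0.14 (0.0346). MAPK9, the stress kinase JNK2, was at least 2.77-fold (0.0331), KIF3B, a kinesin motor, at least 2.17-fold (0.0107) and MCCC2 at least 2.2-fold higher (0.0199), and PIGS rose by 1.25 ± 0.27 (0.0405). COMMD5 was at least 1.88-fold (0.0107), PLXDC1 at least 1.8-fold (0.0388) and NOL4 at least 1.7-fold lower (0.0191), and H2AC14 fell by 1.03 ± 0.21 (0.0331). PDTC vehicle again differed from IL-6 vehicle the same way for MAPK9 (1.42), KIF3B (1.05), COMMD5 (-1.15), PLXDC1 (-0.83) and NOL4 (-0.87). ALB was at 0.02 ± 0.16 and APOA1, the brightest target on all IL-6 arrays, at 0.00 by the construction of the quantile step. In total 64 genes passed, 46 higher and 18 lower.

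The metal list had 2 rises and 8 not called at 8 h of IL-6 (4 adjusted over the list alone; list adjusted p = 0.0046), and in the series value table its test turned to lower (mean 0.055 SD units). The interferon list was called lower (0.0448; adjusted p = 0.332 with an estimated correlation), with a mean of 0.23 under median scaling and of 0.018 SD units in the series value table, with 0 of 14 passing and 0 adjusted over the list alone. An effect of IL-6 on the metal list was again not separated from the gap between the vehicle sets. Between 8 h and 4 h limma called 0 genes (158 at an unadjusted p under 0.05). The count of 64 fell to 17, 4, 1, 3, 3 and 3 under the alternatives in the order given for 2 h. The 1 gene left with median scaling at 2, 4 and 8 h each was higher, as were 3 of 5 and 3 of 3 at 2 and 8 h with quantile normalization within the arm, and 5 of 6 and 3 of 3 at 4 and 8 h in the series value table. The count became 1 without IL-6 vehicle b, 193 without vehicle a, 0 by limma without 8 h a (813 at an unadjusted p under 0.05) and 4 without 8 h b. It was 17, 17, 19 and 18 without PDTC 1 h a, 1 h b, 2 h a or 2 h b, and 151 and 147 without PDTC 8 h a or b. Over the 4 times 170 genes were called at least once and 5 at every time, against 35 at least once without IL-6 vehicle b and 373 without vehicle a.

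In the direct test of PDTC against IL-6 at 1 h, each relative to its own vehicle, 73 genes differed, 55 with the higher change under PDTC. DDIT4 rose under PDTC and fell under IL-6, a difference of 4.59 ± 0.25 (adjusted p = 8.83e-09). MT1B (4.78 ± 0.20, 3.58e-10), HSPA1A (4.52 ± 0.77, 0.0063) and FOS (4.11 ± 0.25, 2.24e-08) were higher under PDTC, and CEBPD (-2.63 ± 0.24, 6.76e-06), DEPP1 (-1.96 ± 0.21, 3.89e-05), SOCS1 (-1.92 ± 0.28, 0.00135) and HAMP (-1.83 ± 0.32, 0.00684) were higher under IL-6.

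Genes called higher in both arms were found at 1 h. Of the 112 genes higher under PDTC and the 35 higher under IL-6 13 were the same, where 0.44 would be shared if the calls were independent (Fisher's exact test, two-sided, adjusted p = 1.97e-15). They were IRF1, ELF3, GADD45B, IER3, NFKBIZ, DNAJB1, EGR1, HMOX1, NUPR1, ID1, ADM, CSRNP1 and 1 unnamed target, listed after their values were seen. Neither arm had a vehicle array at 1 h, so an effect of time in serum-free medium was not separated from the agents. The test treats genes as independent, and both sets of calls come from the same fit with a shared spread for each gene. DDIT4 and ANKRD37 were higher under PDTC and lower under IL-6 (exact test, adjusted p = 0.0535). At 2, 4 and 8 h no overlap passed, whichever the directions (exact tests, adjusted p from 0.244 to 0.907).

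At 2 h of both agents the difference was largest for MT1B (6.24 ± 0.20), HSPA1A (5.83 ± 0.77), FOS (5.28 ± 0.25) and HSPA6 (5.19 ± 0.22) on one side and AXIN2 (-2.26 ± 0.21), ZBTB9 (-1.82 ± 0.27), SP5 (-1.80 ± 0.25) and IRS1 (-1.77 ± 0.36), an adaptor of the insulin receptor, on the other. Their adjusted p ran from 5e-12 to 0.00883. In total 381 genes differed, 198 with the higher change under PDTC. At 4 h they were 1628 (708 higher under PDTC), led by MT1B (7.23 ± 0.20), HSPA6 (6.36 ± 0.22), HSPA1A (5.79 ± 0.77) and PPP1R15A (5.06 ± 0.25). On the other side were SP5 (-2.42 ± 0.25), AXIN2 (-2.39 ± 0.21), ARFGEF1 (-2.02 ± 0.41) and RNF43 (-2.01 ± 0.36), a ubiquitin ligase that removes Wnt receptors. Their adjusted p ran from 4.7e-13 to 0.00354. At 8 h they were 2643 (1178 higher under PDTC), led by MT1B (7.95 ± 0.20), HSPA6 (6.34 ± 0.22), MT1M (6.02 ± 0.20) and PPP1R15A (4.77 ± 0.25). On the other side were MAPK9 (-2.70 ± 0.46), CILK1 (-2.61 ± 0.42), GTF3C2 (-2.57 ± 0.55) and TRIM37 (-2.42 ± 0.59), with adjusted p from 1.02e-13 to 0.00729. FOS, HSPA6, SOCS1, MAPK9, CILK1 and ARFGEF1 were not detected in some of these groups, so their fitted differences depend on the background offset. A gap between the vehicle sets also enters each difference. The IL-6 part was 1.62, 1.07 and 0.93 for MAPK9, CILK1 and TRIM37 at 8 h, and 0.29 for GTF3C2. At 4 h it was 1.07 for ARFGEF1 and 0.75 for RNF43, but 0.12 for SP5 and 0.05 for AXIN2. Opposite effects of the agents were not separated from that gap.

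The counts of differences depended on single arrays and on the scaling. With median scaling they were 16, 2048, 4299 and 5289 at 1, 2, 4 and 8 h, and from 2 h on most were lower under PDTC: only 82, 180 and 208 were higher. Higher at 2, 4 and 8 h were 161 of 661, 574 of 2374 and 930 of 3353 in the series value table. The 73 at 1 h became 41 and 188 without PDTC vehicle a or b, 42 and 44 without PDTC 1 h a or b, 114 and 116 without PDTC 8 h a or b and 47 without IL-6 1 h b. The 381 at 2 h became 151 and 726 without PDTC vehicle a or b, and 152 and 228 without PDTC 2 h a or b. They became 719 and 727 without PDTC 8 h a or b, 192 without IL-6 vehicle b, and 194 and 184 without IL-6 2 h a or b. The 1628 at 4 h became 738 without PDTC vehicle a, 729 without PDTC 4 h b, 910 without IL-6 vehicle b and 831 without IL-6 4 h a. The 2643 at 8 h became 1689 and 1724 without PDTC vehicle a or IL-6 vehicle b.

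The share of IL-6 changed genes that moved the opposite way under PDTC was lowest at 1 h. Of the 45 genes called at 1 h of IL-6 17 had the opposite sign under PDTC (37.8%, against 47.4% of all genes), 3 were called in the opposite direction, DDIT4, ANKRD37 and DEPP1, and 13 in the same direction. At 2, 4 and 8 h the shares were 57.1% of 77, 59.4% of 69 and 65.6% of 64, against 53%, 55.5% and 54.5% of all genes. Of these, 3, 12 and 23 genes were called in the opposite direction and 7, 11 and 12 in the same direction. Toward the level of PDTC vehicle, from which the change under PDTC is measured, 73, 67 and 62 of them had changed. Among all genes it was 69.4%, 70.2% and 68.2%. A gap between the vehicle sets can thus give opposite signs, and opposite effects of the agents were not separated from it. Over the 4 times the sign was opposite for 144 of 255 pairs of a gene and a time, or 56.5%. The Wilson 95% interval, 50.3 to 62.4%, treats these pairs as independent. They are not, since they came from 170 different genes and the times of an arm share its vehicle arrays. The pooled share was 31.6% without IL-6 vehicle b, 39.6% with quantile normalization within each arm, 37.1% in the series value table and 16.7% with median scaling.

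Some fixed lists were not called in any comparison, and their smallest adjusted p is given here. At 8 h of PDTC the endoplasmic reticulum unfolded protein response had 5 rises and 2 falls among 17 (0.261), and complement and coagulation had 9 falls and 0 rises among 23 (0.135). At 4 h of PDTC proteasome subunits had 1 rise and 5 falls among 26 (0.207), and mitochondrial oxidative phosphorylation had 5 falls among 25 (0.276). For the other lists the smallest p was under IL-6, and at that time none of their members passed. At 1 h these were gluconeogenesis and fasting (10 genes, 0.157) and p53 targets (13, 0.198), and at 2 h ribosomal proteins (26, 0.0967). At 8 h they were G1 to S and DNA replication (20, 0.0703), G2 and mitosis (21, 0.265), hepatocyte transcription factors (9, 0.0562) and markers of non-hepatic cell types (5, 0.14). Of the 216 list tests 54 were called, 38 under PDTC and 16 under IL-6, and 34 of them with an estimated correlation, while fry called 88. Calls not given a second p above held with it.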

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

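The tests of single 1 h arrays, of vehicle RNA on the later IL-6 arrays, of the IL-6 list relative to all genes, of the gap between the vehicle sets and of the fit without PDTC vehicle a and PDTC 8 h a were chosen after the results they measure were seen. The others below were written down before. Counts that differed between groups or times by a test of the difference itself are given first.

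Under PDTC 67 genes differed between 2 h and 1 h, 190 between 4 h and 2 h, and 1155 between 8 h and 4 h. Under IL-6 50 genes differed between 2 h and 1 h. The change under PDTC differed from that under IL-6 for 73 genes at 1 h, 381 at 2 h, 1628 at 4 h and 2643 at 8 h.

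IL-6 target genes were higher at 1 h and no longer at 2, 4 or 8 h, where IRF1, HAMP, CEBPD and HP no longer passed. A single deviant array is argued against: over the IL-6, JAK and STAT3 list the mean log2 change was 0.527 with 1 h a and 0.599 with 1 h b, with an SD of 0.063 between arrays. Vehicle RNA on the later arrays stays open. The metal response list had a mean change of 0.455, 0.428 and 0.278 at 2, 4 and 8 h with a standard error of 0.04, and its bound had been set at 0.2. That bound was too low, since PDTC vehicle, also untreated, lay 0.47 above IL-6 vehicle for this list. Background correction or normalization that acts on these genes apart from the others is argued against: relative to the median of all genes, the list at 2, 4 and 8 h reached at most 0.037 of its value at 1 h under any alternative. It lay below 0.5 of that value by more than 2 SD of single arrays under each. A shift of all genes together stays open, since quantile normalization removes it: with median scaling the later mean of the list reached 0.489 of that at 1 h, where the median of all genes had itself moved by 0.408. A short-lived response is the biological candidate, and the design has no group that tests it apart from these arrays.

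The IL-6 calls at 2, 4 and 8 h came mostly from dim genes, 87%, 75.4% and 84.4% of them below the median brightness of the tested genes. A source in the background estimate of dim probes had the values it needs: without background correction the counts were 0.182, 0.319 and 0.062 of those reported. The loss was not particular to that step, since quantile normalization within the arm, with the same background, left 5, 9 and 3 genes. IL-6 vehicle arrays that stand apart from the others also had the values this needs. IL-6 vehicle b had the fewest detected targets of all arrays, 6839, and the lowest mean signal, 225. Treated arrays came close to these values, IL-6 1 h a with 6936 targets and IL-6 4 h b with a mean signal of 226. Leaving out IL-6 vehicle b lowered the counts at 2, 4 and 8 h, and leaving out vehicle a raised them. Of the 77, 69 and 64 genes 73, 67 and 62 had changed toward the level of PDTC vehicle, against 69.4%, 70.2% and 68.2% of all genes, counts that share the IL-6 vehicle arrays. With equally many genes picked on the arrays of one letter and measured on the other, PDTC vehicle lay from IL-6 vehicle at 1.089 to 1.778 times the later IL-6 change. At 1 h it was -0.207 and 0.592 times. Why the vehicle sets differ was not tested, and arm and batch cannot be told apart there. Chance spread of single arrays stays open, because the changes from the a arrays and from the b arrays, which share no array, correlated across genes with r of only 0.278, 0.382 and 0.312 at 2, 4 and 8 h, and -0.009 at 1 h. Genes are not independent replicates, and a real response at low level may add to these calls, which was not tested. MT1X, bright and higher at all 3 times, is not among the dim genes, but PDTC vehicle lay above IL-6 vehicle for it by 0.75 ± 0.13, and it did not pass in the series value table (0.685 to 0.859 SD units).

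PDTC vehicle a and PDTC 8 h a stood apart from the other arrays in a principal component analysis. That the 8 h change comes from these arrays is argued against by the change from vehicle b to 8 h b, which correlated with that from vehicle a to 8 h a across genes with r of 0.792. Loss of short abundant transcripts stays open: ribosomal protein genes were lower in a than in b by -0.116 in vehicle and by -0.28 at 8 h. Without these arrays 94, 266, 1393 and 1411 genes were called at 1, 2, 4 and 8 h of PDTC, where a lone vehicle array and a lone 8 h array are assumed to vary like the other groups. No biological explanation was tested for arrays of the same group.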

How the results depend on the processing

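The alternatives with the background from all targets, with detection from the signal and without PDTC vehicle a and 8 h a were chosen after the data were seen, the others before. For every value that moved the cause was not tested. Named genes and called lists were compared under the alternatives that apply to them and keep them. In this comparison 8520 gene values and 1824 list values kept their side of the threshold, and those called in the results above also kept their direction. For genes called neither there nor under the alternative the direction was not compared. Of the rest 526 and 113 fell short of the threshold and 72 and 0 passed it. Reversed were STAT3 at 8 h of PDTC with median scaling (-0.141), where the median of all genes was -0.678. In the series value table APOA1 (0.85) and ALB (0.29) at 8 h of PDTC reversed, as did negative acute phase proteins at 8 h of PDTC (0.164) and the metal list at 8 h of IL-6 (0.055). The mean of all probes, a 1.5-fold threshold and detection from the signal left every count within 1.5 times. Signal over background limits dim genes: background means were 90.4 to 123 and median signals 101.5 to 142. PDTC counts at 4 and 8 h and list calls were steadier than IL-6 counts at 2, 4 and 8 h.

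With an offset of 50 the count at 1 h of PDTC was 253, those at 2, 4 and 8 h of IL-6 were 18, 32 and 17, and 85 genes were called at any time of IL-6. Without background correction these were 283, then 14, 22 and 4, and 63, and 45% of IL-6 genes had the opposite sign under PDTC. With the background from all targets these were 265, then 6, 20 and 2, then 52 and 38.1%. Median scaling gave 49 and 235 at 1 and 2 h of PDTC, and 15, 1, 1 and 1 at the times of IL-6 with 16 at any time. Its differences between arms were 16, 2048, 4299 and 5289, and its opposite share 16.7%. Quantile normalization within each arm gave 5, 9 and 3 at 2, 4 and 8 h of IL-6, 47 at any time and a share of 39.6%. The series value table gave 26, 0, 6 and 3 for IL-6 (at 2 h 1591 at an unadjusted p under 0.05 by limma), 33 at any time, 661 differences at 2 h and a share of 37.1%.

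Without a detection filter, with 18683 genes tested, 122 were called at 2 h of IL-6. Detection on all 20 arrays, with 5634 genes tested, gave 7, 12 and 3 at 2, 4 and 8 h of IL-6 and 43 at any time. It gave 1688 differences at 8 h and a share of 30.8%. A trended and robust spread gave 243 at 1 h of PDTC. Each arm fitted alone gave 80 and 299 at 1 and 2 h of PDTC, 28 at 8 h of IL-6 and a share of 62.8%. The letters as a block gave 25 at 8 h of IL-6. Array weights gave 265, 1175 and 1820 at 1, 2 and 8 h of PDTC. They gave 116, 113 and 33 at 2, 4 and 8 h of IL-6, and 656 and 1440 differences at 2 and 8 h. The estimated correlation left 34 list calls. The F test called 100 genes for IL-6. Without PDTC vehicle a and 8 h a, 94, 266, 1393 and 1411 genes were called for PDTC and 2052 at any time. For IL-6 it was 250, 215 and 167 at 2, 4 and 8 h and 432 at any time, and 1202 differences remained at 8 h.

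With each array left out in turn, the PDTC counts ranged from 66 to 533 at 1 h, 196 to 1095 at 2 h, 944 to 2716 at 4 h and 2252 to 4258 at 8 h. Those of IL-6 ranged from 28 to 70, 3 to 216, 1 to 256 and 0 to 193. The differences ranged from 41 to 188, 151 to 727, 729 to 2184 and 1689 to 3593. Genes at any time ranged from 2641 (without PDTC vehicle a) to 5179 for PDTC and from 35 to 391 for IL-6. The IL-6 count at any time moved by over 1.5 times without IL-6 vehicle a (373) or b (35), IL-6 2 h a (111) or b (111), PDTC 2 h b (112), and PDTC 8 h a (391) or b (380). The opposite share ranged from 31.6 to 60.6% and list calls from 45 to 54. The lone array left in a group was assumed to vary like the other groups.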

Other observations

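The test of further Wnt target genes was written down after AXIN2, SP5, DKK1 and RNF43 were seen and before its own values were. All other values in this part were looked up after the report's comparisons were made.

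Some further changes are given here, in part for genes already named above. BHLHE40, a repressor linked to circadian and hypoxic responses, was lower than vehicle at 2 h of IL-6, which was not separated from the gap between the vehicle sets. Under PDTC BHLHE40 rose by 1.58 ± 0.17, 2.85 ± 0.17 and 1.65 ± 0.17 at 2, 4 and 8 h. From 4 to 8 h it came down by -1.20 ± 0.18 (adjusted p = 0.00041). CLK1, lower at 1 h of IL-6, was higher at 2, 4 and 8 h of PDTC by 1.18, 1.20 and 0.96 (± 0.19 each). IRS1, an adaptor of the insulin receptor, fell by 1.37 ± 0.25, 1.30 ± 0.25 and 0.92 ± 0.25 at those times, and ABCB1, the drug efflux pump, rose by 0.49 ± 0.14 and 0.87 ± 0.14 at 4 and 8 h. DEPP1, which FOXO factors induce, fell in both arms at 2, 4 and 8 h and in the PDTC arm alone at 1 h, where it rose by 0.72 ± 0.15 under IL-6. Its falls under IL-6 were not separated from the gap between the vehicle sets.

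AXIN2, SP5, DKK1 and RNF43, all of them Wnt targets, fell under PDTC, which raised the hypothesis that PDTC lowers beta-catenin targets as a set. A list of 25 further targets without these genes was drawn up from textbook knowledge, and 12 of them were tested. At 2, 4 and 8 h of PDTC 1, 2 and 2 of them fell and 0, 1 and 2 rose, with a mean log2 change of -0.10, -0.20 and -0.20. The list was not called lower at any of these times (camera p of 0.449, 0.285 and 0.486), so the fall predicted for the set was not called. ABCB1, which rose, is a member of it. With 12 of 25 targets tested and negative means, a moderate fall of the set is not excluded. At 8 h AXIN2 was itself near vehicle again.

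The vehicle arrays of the arms differed in 3123 genes. A deviation of either set enters the changes of its own arm. Since the arms were exported separately, arm and batch cannot be told apart.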
